A study of Mus musculus with 4 samples.

How the data were processed

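The counts are the ones deposited for 4 inDrop libraries of mouse pancreatic islet cells, whole numbers per gene and barcode that were not normalized. Single cells were captured in droplets, their RNA was amplified by the linear CEL-Seq route, and a NextSeq500 read both ends of the fragments, with a kit for 75 cycles per end and read lengths set by the submitters. Libraries whose titles end in _2426 are called A and those ending in _3165 B, after their labels. The submitters' processing notes name the builds GRCh38 and GRCm38. The aligner, the gene annotation, the counting program, the collapsing of molecular barcodes and the rule by which barcodes were kept are not given in the sources used here. Genes carry mouse symbols. Of 38459 features 38457 were marked as mouse, and the other 2, with 2, 2, 2 and 0 counts in the order WT A, mutant A, WT B, mutant B, were left out. The series describes 2 biological replicates per genotype, so the p-values measure the spread between these libraries. Libraries of a group differed by more than counting error, with a chi-square per degree of freedom of 87.9 in those labelled WT and 189 in those labelled mutant.

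Barcodes with at least 500 counts, at least 250 genes and at most 25% mitochondrially encoded counts were kept, and Scrublet was run on each library. Of 6948 barcodes 6566 passed, and 40 (0.61%) were called doublets and removed, 13, 3, 7 and 17 per library. Kept were 1207, 1144, 1793 and 2382 cells. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components and 15 neighbours gave 23 Leiden clusters at resolution 1 with seed 1. No correction between libraries was applied before clustering.

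Clusters were named from marker lists of 18 cell classes, fixed before the data were examined, by the class with the highest marker score. A name needed at least 3 detected markers of the class. A cluster whose median depth was under 0.333 times that of its libraries and that had no own marker among its top 10 genes stayed unnamed, as did one led by markers of granulocytes. A further rule, a marker score under 0.5 with no own marker among the top 10 genes, was set after the data were seen and left 1 cluster of 22 cells unnamed. A cluster of 488 beta-like cells whose top genes were led by proliferation markers was kept apart as cycling beta-like. Most alpha-like cells of B lay in cluster 0, with 396 and 297 cells, and most of those of A in cluster 12, with 106 and 91.

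Counts were summed per library and class, for classes with at least 20 cells in every library and for all cells, so that the library was the unit of each test. The comparisons of the cycling beta-like, pp-like, endothelial-like and mesenchymal-like sums followed the same rule. Libraries labelled mutant were compared with those labelled WT by edgeR's quasi-likelihood F test, with TMM factors, edgeR's filter on low counts, and Benjamini-Hochberg adjusted p under 0.05. The SE of a log2 difference, for genes and for numbers of cells, is its absolute size divided by the square root of edgeR's F. That F draws on the spread of all genes or classes tested, so the SE is not the spread of the 2 libraries of a label and can be smaller. DESeq2 was run on the same sums. Gene names in the report follow a rule fixed before the data were examined: Sin3a, then up to 10 genes per direction past the threshold, or the 5 of smallest unadjusted p where fewer passed, and in beta-like cells the 2 members of smallest p in each gene list. Predicted genes were passed over, and a few genes that the rule took are not reported here and were not replaced.

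Gene lists, 20 in number and fixed before the data were examined, covered the Sin3 complex, islet transcription factors, prohormone processing, glucose sensing, calcium handling, vesicles and exocytosis, endoplasmic reticulum stress, apoptosis and p53, the cell cycle, genes disallowed in beta cells and glycolysis. The others covered oxidative phosphorylation, mitochondrially encoded genes, immediate early and dissociation genes, interferon and MHC genes, sterol synthesis, oxidative stress, non-beta hormones, neuronal REST targets and hemoglobin. They were tested by camera with a preset correlation of 0.01, adjusted over the 20 lists, and again with an estimated correlation and by fry.

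Changes within a number are log2 ratios of CPM for genes with at least 20 counts in each library. For lists they were taken relative to the median gene and set among 10000 random lists of the same size drawn from 20 bins of mean expression. These changes and the list of genes with opposite changes (at least 50 counts) were chosen after the data were seen. Cycling cells held at least 2 counts over 8 markers after thinning to 2000 counts. Insulin-rich cells outside the beta-like classes held at least 0.5 times the median insulin share of the library's beta-like cells. Numbers of cells per class were tested by edgeR with the library's cells as total, and single values by exact permutation.

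On simulated beta-like sums with 2 against 2 libraries and the dispersion fitted for each gene (median 0.233), edgeR recovered 0 of 67, 0 of 67 and 0 of 66 genes set 1.5-fold, 2-fold and 4-fold apart, with 0 false calls. With a dispersion of 0.02 it recovered 12 (17.9%), 41 (61.2%) and 65 (98.5%), with 10 false calls.

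Alternatives were other scalings (DESeq2 size factors, library totals), DESeq2's own test, other filters on low counts and on cells, doublets kept, resolutions of 0.5 and 2, and classes by the most abundant hormone. Sums were also thinned to the smallest library, the number was used as a block, and each library was left out in turn. Added after the data were seen were cycling cells joined to their class and insulin-rich cells left out. Python 3.11.15, scanpy 1.11.5, leidenalg 0.10.2, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used.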

Results

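Pancreatic islet cells of mice labelled WT or Sin3A mutant were profiled by inDrop, a droplet method that tags the 3′ ends of messenger RNAs of single cells. The series holds 2 libraries per genotype, described as 2 biological replicates, and each title ends in a number that occurs once in each genotype. Libraries whose titles end in _2426 are called WT A and mutant A, and those ending in _3165 WT B and mutant B, letters that stand for the labels only. What the numbers mean is not given in the sources used here. The library labelled WT A held 1302 barcodes and 12835199 counts, and the library labelled mutant A held 1323 barcodes and 9282495 counts. The library labelled WT B held 1878 barcodes and 10350699 counts, and the library labelled mutant B held 2445 barcodes and 12236110 counts. After the cell filters 6526 cells remained, with median counts per cell of 9997, 7605, 5306 and 4448.5 in the order WT A, mutant A, WT B, mutant B. That order of libraries is used for every run of 4 values. The cells fell into 23 clusters, of which beta-like cells, the insulin producers, were the most numerous class with 2183 cells, followed by 946 alpha-like cells and 807 mesenchymal-like cells.

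Sin3a, the targeted gene, encodes the scaffold of a histone deacetylase corepressor complex. It was higher in the library labelled mutant than in the library labelled WT within A, and lower within B. In beta-like cells it stood at 25.7, 42.9, 40.9 and 17.7 CPM (counts scaled to 1e6 per library and class), from 157, 201, 164 and 80 counts. The 95% Poisson intervals were 21.82 to 30.02, 37.14 to 49.21, 34.84 to 47.61 and 14.03 to 22.02 CPM and cover counting error only. The ratio of labelled mutant to labelled WT was thus 1.67 within A and 0.433 within B. Alpha-like cells gave ratios of 1.52 and 0.491, delta-like cells 2.23 and 0.666, endothelial-like cells 1.53 and 0.522, and ductal-like cells 2.77 and 0.369. These rest on 42, 38, 92 and 32 counts in alpha-like, 44, 42, 12 and 22 in delta-like, 17, 30, 29 and 17 in endothelial-like and 7, 11, 34 and 19 in ductal-like cells. The Poisson intervals overlapped within A in alpha-like, endothelial-like and ductal-like cells, and within B in delta-like and endothelial-like cells. In mesenchymal-like cells Sin3a was at 19.3, 55.8, 21.5 and 22.2 CPM, ratios of 2.89 and 1.03. Summed over all cells the 4 libraries held 27.5, 54.1, 43.5 and 21.3 CPM.

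Over both A and B Sin3a differed by -0.02 ± 0.61 (SE, log2) in beta-like cells between the libraries labelled mutant and those labelled WT (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.0). The gene (ENSMUSG00000042557) lies on chromosome 9 from 57072040 to 57128366 on the plus strand in GENCODE release M21 on GRCm38, and its annotated transcript has 20 exons, the last from 57127148 to 57128366. Tags come from the 3′ ends of transcripts, and the labels do not say which part of the gene was changed or in which cells. A tag outside the changed part is counted from a mutant transcript as well and checks nothing. The higher Sin3a in the library labelled mutant within A therefore neither bears out nor refutes the label. Groups are named by their labels throughout, and each direction below is that of the labels.

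**Figure D1:**
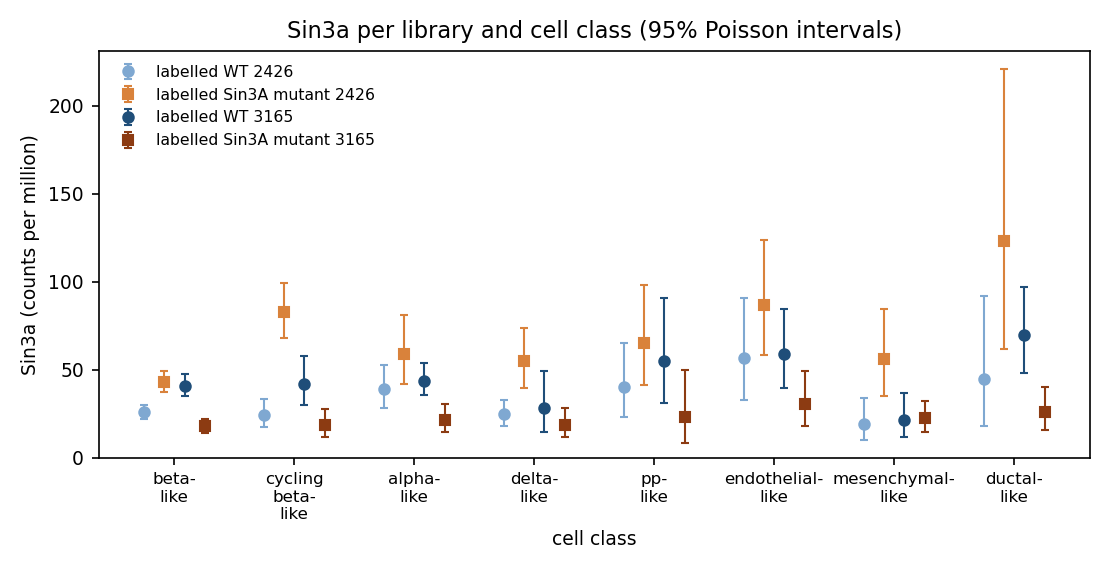
A and B stand for titles ending in _2426 and _3165. Sin3a level (CPM of the class's summed counts, vertical axis) in 8 cell classes (horizontal axis) for each of the 4 libraries, with 95% Poisson intervals that cover counting error only. In beta-like cells the libraries labelled WT A and mutant B sit at 25.7 and 17.7, below the libraries labelled mutant A and WT B at 42.9 and 40.9.

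Beta-like cells were compared to find which genes differ with the genotype label. No gene passed in either direction. On simulated sums with the fitted dispersion this test recovered 0 of 66 genes set 4-fold apart. A count of 0 therefore does not show that genes are unchanged. The counts of 0 in the classes below also rest on 2 libraries per label. Cldn11, a claudin of tight junctions, stood at 26.5, 6.61, 29.1 and 458 CPM, a log2 difference of 3.15 ± 1.16 (SE derived from edgeR's F, n = 2 libraries per label). This SE is not the spread of the 2 libraries of a label: the change was -1.96 within A and 4.14 within B. Spink13, a protease inhibitor of the Kazal type, was at 3.93, 5.33, 3.24 and 34.1 CPM, and Zfp773, a zinc finger gene, at 5.23, 5.97, 8.72 and 76.1 CPM. Fhl2, a LIM domain cofactor, was higher in the labelled mutant of both numbers, at 8.34, 19.6, 7.72 and 24.3 CPM, a log2 difference of 1.54 ± 0.63. Pianp was at 8.995, 68.7, 2.74 and 1.77 CPM.

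On the lower side, Tmsb15b1, an actin-binding thymosin, stood at 53.6, 13.9, 20.2 and 3.98 CPM, a log2 difference of -1.99 ± 0.75. It has a near-identical paralog, so its counts are uncertain. Ckb, the brain-type creatine kinase, was at 69.7, 24.7, 23.4 and 6.86 CPM, lower in the labelled mutant of both numbers. Clrn3 was at 4.42, 0.853, 2.99 and 1.33 CPM, from as few as 4 counts, and Tmprss2, a membrane serine protease, at 2.29, 3.20, 22.9 and 2.43 CPM.

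Of 14916 genes tested in beta-like cells, 0 passed an adjusted p of 0.05 with edgeR, while 16 were higher and 1 lower at an unadjusted p under 0.05, and DESeq2 called 0 with 15 and 2 unadjusted. If no gene differed, a share of about 0.05 would lie under that unadjusted p, so these counts are far fewer than that. Split by number, the same sums gave 809 and 1324, and the remaining split gave 914 and 842. Unadjusted counts of the label comparisons in the classes below lay under that share as well. Leaving out the library labelled WT A let Mir6240 pass as higher, and leaving out the library labelled mutant A let Cldn11 pass at a log2 difference of 4.13, names given after their values were seen. Different clusters held most of the class in each library: 401 of 447 cells of cluster 6 came from WT A, 433 of 459 of cluster 5 from mutant A, 565 of 588 of cluster 2 from WT B and 645 of 689 of cluster 1 from mutant B.

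Across the 9902 genes with at least 20 counts in every library, the change from labelled WT to labelled mutant within A ran opposite to that within B in beta-like cells, with Pearson r = -0.72. This correlation is across genes, which are not independent replicates, and no library enters both changes. At least 2-fold relative to the median gene, 310 genes were higher in the labelled mutant of A and lower in that of B, 267 the reverse, 3 higher in both and 1 lower in both. Ucn3, a peptide released by mature beta cells, stood at 204, 458, 981 and 241 CPM. Insrr, the insulin receptor-related receptor, was at 14.4, 98.3, 169 and 19.0 CPM, Prss53 at 107, 421, 320 and 42.0 CPM, and Rnase4 at 32.1, 203, 383 and 62.8 CPM. The other way round were Spp1, a secreted phosphoprotein, at 120, 15.1, 13.5 and 254 CPM, Pyy, a peptide hormone, at 5917, 1187, 1063 and 4386 CPM, and Myc, a growth regulator, at 87.3, 17.9, 26.2 and 127 CPM. These 7 were chosen after their values were seen. Spp1 and Pyy are also among the markers used for ductal-like and pp-like cells, and Pyy made up 3.22% to 6.16% of counts in delta-like cells. Whether RNA of such cells adds to their beta-like counts was not tested for these genes. The remaining classes with at least 20 cells in every library gave r of -0.615 in the cycling beta-like cluster, -0.602 in delta-like, -0.568 in alpha-like, -0.371 in pp-like, -0.242 in mesenchymal-like and -0.201 in endothelial-like cells. Many delta-like cells were insulin-rich, and without these r was -0.475 in that class.

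**Figure D2:**
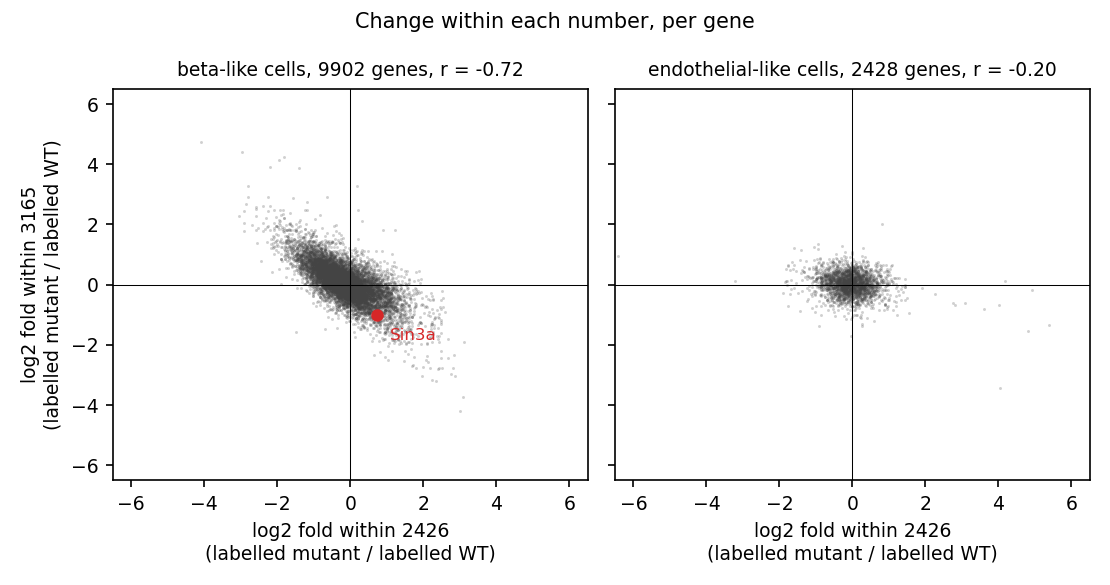
A and B stand for titles ending in _2426 and _3165. Each point is a gene with at least 20 counts in every library, placed by its log2 fold of labelled mutant over labelled WT within A (horizontal axis) and within B (vertical axis), in beta-like cells (left, 9902 genes, r = -0.72) and endothelial-like cells (right, 2428 genes, r = -0.201). Sin3a is marked in red in the lower right of the beta-like panel.

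By gene list, camera called non-beta hormones higher and endoplasmic reticulum stress genes lower in the beta-like cells of the libraries labelled mutant, and neither call held with an estimated correlation (adjusted p = 0.668 and 0.918). Of 9 measured non-beta hormone genes 8 were higher, with a median log2 difference of 0.89 (camera, adjusted p = 5.755e-06; adjusted p = 0.668 with an estimated correlation). Gcg, the glucagon gene, stood at 620, 3414, 2269 and 1398 CPM against 10.5% to 19.1% of all counts in alpha-like cells. Ppy was at 29.8, 110, 118 and 145 CPM, Gast at 1.80, 3.63, 0.996 and 3.76 CPM, and Ghrl at 1.15, 9.60, 2.74 and 1.77 CPM, while Pyy was the member that was lower. Tph1, which encodes the enzyme that starts serotonin synthesis and is not itself a hormone gene, was at 38.6, 4.48, 3.99 and 120 CPM. The call ended without the library labelled WT B (camera, adjusted p = 0.0569) and without the library labelled mutant B (0.521).

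Of 26 measured stress response genes 20 were lower, with a median log2 difference of -0.13 (camera, adjusted p = 0.0271; adjusted p = 0.918 with an estimated correlation). Within A 6 of 25 members were higher and 19 lower relative to the median gene (median -0.47), and within B 17 were higher and 8 lower (0.17). Asns, asparagine synthetase, stood at 37.6, 21.1, 24.9 and 14.8 CPM, and Xbp1, a transcription factor of this response, at 172, 159, 357 and 170 CPM. The call ended without the library labelled WT A (adjusted p = 0.412) or WT B (0.0707), and turned upward without mutant A (0.525). Fry, which tests whether the genes of a list move one way on balance without comparing them with other genes, gave adjusted p of 0.365 for the hormones and 0.970 for the stress response. Leaving out WT A, mutant A, WT B or mutant B moved the count of lists past camera's threshold from 2 to 4, 3, 5 and 2. Adjusted over the list alone, 0 members passed in any of the 20 lists with edgeR.

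The other 18 lists did not pass camera in beta-like cells. Adjusted p was 0.362 for vesicle and exocytosis genes, immediate early genes, interferon and MHC genes and neuronal REST targets. It was 0.460 for glycolysis, 0.604 for glucose sensing and for genes disallowed in beta cells, and 0.613 for the Sin3 complex and for hemoglobin. Cell cycle, oxidative phosphorylation and mitochondrially encoded genes had 0.634, oxidative stress 0.674, prohormone processing and calcium handling 0.796, apoptosis and p53 0.859, and islet transcription factors and sterol synthesis 0.942. Median, mean and test differed in sign for the Sin3 complex, islet transcription factors, prohormone processing, apoptosis, oxidative stress and hemoglobin.

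Of the members nearest to the threshold in those lists some ran opposite within the numbers and some the same way. Pfkm, a phosphofructokinase, stood at 22.6, 14.5, 18.4 and 12.2 CPM, Gadd45a, a gene of the DNA damage response, at 32.2, 27.1, 48.8 and 22.6 CPM, and Rims2, a protein of exocytosis, at 4.42, 8.74, 11.2 and 12.6 CPM. Ogt, the O-GlcNAc transferase bound by the Sin3 complex, stood at 11.4, 43.3, 19.7 and 7.30 CPM, and Ing1, a subunit of that complex, at 177, 54.4, 101 and 323 CPM. Cox7c of the respiratory chain was at 410, 181, 459 and 1115 CPM, Cdkn1a, a cell cycle inhibitor, at 37.0, 26.9, 24.4 and 83.4 CPM, and Vamp2, a vesicle fusion protein, at 87.2, 147, 37.4 and 22.8 CPM. Mt1, a metallothionein, was at 2.78, 56.3, 34.1 and 2.21 CPM. The heat shock genes Hspa1a and Hspa1b, near-identical copies whose counts are uncertain, were at 1.96, 27.7, 349 and 46.2 CPM and at 2.94, 26.2, 916 and 175 CPM. Ryr2, a calcium release channel, was at 2.94, 11.5, 3.49 and 3.10 CPM.

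Within the numbers, where each label has 1 library and no test is possible, the immediate early and dissociation list, with Fos, Ier2 and Nr4a1, differed in opposite directions. All 17 members with at least 20 counts per library were higher in the labelled mutant of A and all 17 lower in that of B, relative to the median gene, with list medians of 0.78 and -0.63 (log2). These medians lay at percentiles 100 and 0 of 10000 random lists of the same size and mean expression, which describes these libraries only. Mitochondrially encoded genes had medians of -0.39 and 0.59 at percentiles 9.33 and 99.8, and oxidative phosphorylation genes -0.32 and 0.31 at percentiles 6.43 and 98.3. Median mitochondrial shares of counts per cell, a sign of RNA quality, were 4.68%, 3.25%, 5.89% and 7.06% over all kept cells, not beta-like cells alone. With at most 10% mitochondrial counts and clusters made anew, beta-like cells numbered 490, 590, 646 and 368, against 440, 467, 590 and 686. Only the library labelled mutant B thus lost beta-like cells under that limit.

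**Figure D3:**
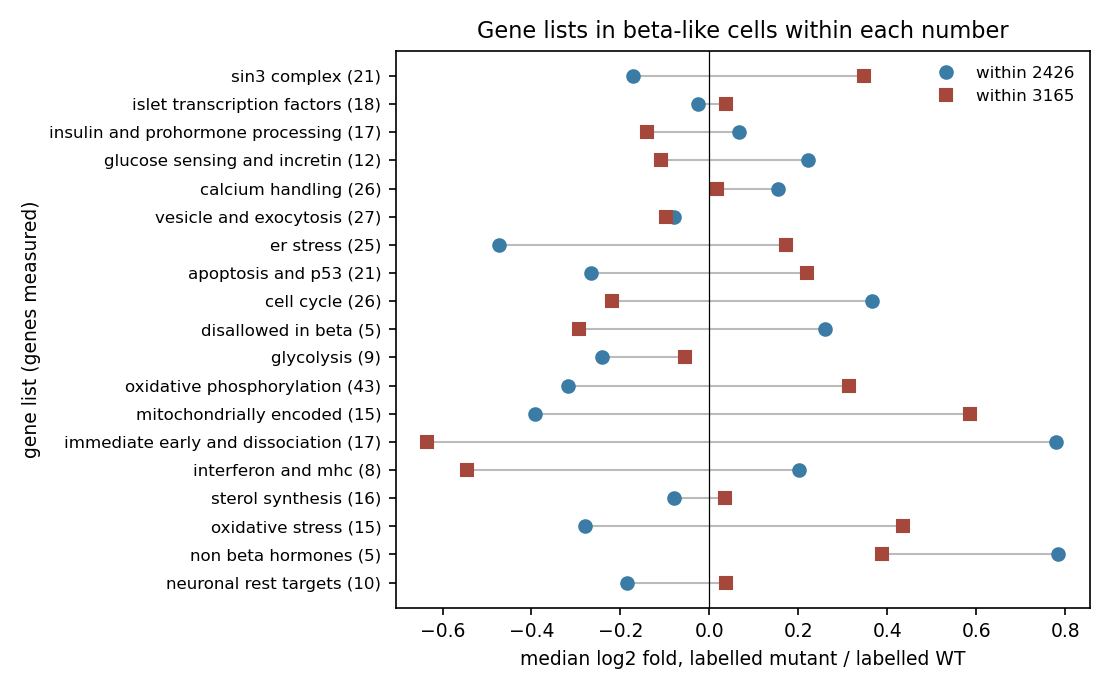
A and B stand for titles ending in _2426 and _3165. Median log2 fold of labelled mutant over labelled WT in beta-like cells (horizontal axis) for each gene list (vertical axis, measured genes in brackets) within A (circles) and within B (squares), relative to the median gene. Immediate early genes lie at 0.78 and -0.63, mitochondrially encoded genes at -0.39 and 0.59.

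Insulin transcripts made up 15.2%, 28.9%, 8.55% and 4.26% of beta-like counts. Ins1 stood at 82222, 173660, 39945 and 18453 CPM and Ins2 at 69382, 115650, 45535 and 24152 CPM. The share was 11.9% ± 4.68 (SD, n = 2) in the libraries labelled WT and 16.6% ± 17.4 (SD, n = 2) in those labelled mutant, a difference of 4.74 percentage points (two-sided exact permutation test, p = 1.0). With 2 against 2 libraries an exact permutation test cannot go below p = 0.333. Without the library labelled mutant A the difference turned to -7.59, and without mutant B it was 17.1.

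Alpha-like cells, the glucagon producers, showed no gene past the threshold either. Lmtk3, a membrane kinase, stood at 25.1, 32.7, 168 and 12.8 CPM, a log2 difference of -2.25 ± 0.83 (SE), and Sytl4, the granule protein granuphilin, at 51.0, 4.67, 14.3 and 9.40 CPM. Ins2 was at 5477, 1184, 765 and 263 CPM there, against 24152 to 115650 CPM in beta-like cells. Insulin-rich cells made up 6.62% of the alpha-like cells of the library labelled WT A and at most 0.66% of those of the remaining libraries. Bach2, a transcription factor, was at 7.43, 24.9, 7.61 and 18.8 CPM, Glra3, a glycine receptor subunit, at 4.64, 10.9, 1.90 and 16.8 CPM, and R74862 at 21.3, 94.9, 11.4 and 16.8 CPM. Few counts lie behind the lowest of these, as Sin3a at 38.98, 59.1, 43.74 and 21.48 CPM had 42, 38, 92 and 32 counts there. With edgeR 0 of 10418 genes passed, against 5 higher and 5 lower at an unadjusted p under 0.05, and DESeq2 gave 0 with 9 and 7 unadjusted. Leaving out the library labelled mutant A gave 8 lower genes, among them Ins1, Ins2, Lmtk3, Dio1 and Tmsb15b1, and leaving out WT A gave 1 higher gene, Mir6240. None of the 20 lists passed camera. Oxidative phosphorylation was nearest, lower in 33 of 43 genes (adjusted p = 0.0758), and the remaining lists lay between 0.102 and 0.985. Median and mean differed in sign for the interferon and MHC list there. The oxidative phosphorylation list passed without the library labelled mutant A (camera, adjusted p = 0.00159) or WT B (0.000331), and leaving out WT A, mutant A, WT B or mutant B gave 1, 1, 4 and 2 lists.

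The genotype difference itself was set against cell class in a model of beta-like and alpha-like sums. With edgeR 0 of 15225 genes differed in their change between alpha-like and beta-like cells, with 74 higher and 139 lower in alpha-like cells at an unadjusted p under 0.05. Without the library labelled WT A, 1 gene and 6 genes passed in the respective directions, and without WT B or mutant B, 0 and 3. Without a filter on low counts 0 and 6 passed.

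Delta-like cells, which make somatostatin, held Tmsb15b1 as the gene nearest to the threshold, at 51.7, 11.7, 49.3 and 2.56 CPM, a log2 difference of -2.84 ± 0.79 (SE, edgeR, unadjusted p = 0.00311, adjusted p = 1.0). Ghrl, the ghrelin gene, stood at 47.8, 24.7, 77.5 and 4.27 CPM, and Dct, dopachrome tautomerase, at 52.9, 15.6, 49.3 and 21.3 CPM. Scn9a, a sodium channel, was at 60.6, 100, 28.2 and 108 CPM, Cldn11 at 33.9, 52.1, 68.1 and 235 CPM, and Bag2, a chaperone cofactor, at 17.8, 22.1, 9.39 and 68.3 CPM. The lowest of these values rest on few counts, as Sin3a at 24.48, 54.67, 28.17 and 18.77 CPM had 44, 42, 12 and 22 counts there. With edgeR 0 of 9614 genes passed, against 4 higher and 5 lower at an unadjusted p under 0.05, and DESeq2 gave 0 with 3 and 3. Insulin-rich cells made up 53.0%, 45.7%, 0.0% and 34.4% of this class, and without the library labelled WT A edgeR called 15 higher genes.

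A cluster of beta-like cells led by cell cycle genes such as Ube2c, Ccnb1 and Top2a was tested apart. Spink13 stood there at 2.62, 8.25, 2.20 and 51.6 CPM, a log2 difference of 3.65 ± 0.98 (SE), and Sst, the somatostatin gene, at 180, 393, 222 and 919 CPM against 51550 to 81470 CPM in delta-like cells. Smpd3, a sphingomyelinase, was at 48.5, 15.8, 31.9 and 11.9 CPM, and Tmem67, a protein of cilia, at 36.7, 228, 35.2 and 32.6 CPM. Sin3a at 24.26, 82.52, 41.85 and 18.27 CPM had 37, 110, 38 and 23 counts in this cluster, so the lowest CPM rest on few counts. With edgeR 0 of 10276 genes passed, against 21 higher and 3 lower at an unadjusted p under 0.05, and DESeq2 gave 0 with 24 and 1. Leaving out the library labelled mutant B gave 35 higher and 2 lower genes, mutant A 4 higher and WT A 1 higher.

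Among all beta-like cells, cycling ones included and each thinned to 2000 counts, 18.3%, 14.98%, 14.6% and 15.9% held at least 2 counts of 8 proliferation markers, from 536, 534, 664 and 810 cells. Exact binomial intervals at 95% were 15.1 to 21.8%, 12.1 to 18.3%, 12 to 17.5% and 13.5 to 18.6%. Left out as shallower were 15, 54, 27 and 31 cells, and without thinning the shares were 34.3%, 31.3%, 25.2% and 27.0%. Delta-like cells, measured the same way, gave 6.47%, 3.70%, 6.67% and 5.52%, and endothelial-like cells 18.9%, 13.3%, 20.6% and 14.4%, values not tested. The difference of -0.992 percentage points between labels was within the spread of the libraries labelled WT (16.4% ± 2.60 against 15.5% ± 0.668, SD, n = 2 each, two-sided exact permutation test, p = 1.0). Its sign turned under all 4 alternative cell filters, and also without the library labelled WT A, where it was 0.845.

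Pp-like cells, the pancreatic polypeptide producers, had 0 of 5251 genes past the threshold with edgeR, with 7 higher and 6 lower at an unadjusted p under 0.05, and 0 with DESeq2, with 3 and 2. Chic1 stood at 166, 344, 180 and 490 CPM, a log2 difference of 1.26 ± 0.48 (SE), Arhgap12 at 10.1, 51.2, 22.0 and 83.6 CPM, and Abcc4, a drug transporter, at 15.1, 42.6, 7.35 and 57.0 CPM. Low CPM rest on few counts here: 16, 23, 15 and 6 counts of Sin3a made 40.25, 65.36, 55.08 and 22.8 CPM. Tmsb15b1 was at 128, 51.2, 110 and 15.2 CPM, and the differentiation inhibitors Id2 and Id3 were at 133, 36.9, 103 and 60.8 CPM and at 37.7, 22.7, 165 and 26.6 CPM. Without the library labelled mutant B edgeR called 8 higher and 2 lower genes, without WT A 5 and 1, and without mutant A 0 and 1.

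In endothelial-like cells the lower genes nearest to the threshold were Ube2c, Ccnb1, Trappc13, Ccna2 and Ackr3. Ube2c, a ubiquitin-conjugating enzyme of mitosis, stood at 136, 14.4, 130 and 39.6 CPM, a log2 difference of -2.16 ± 0.53 (SE), Ccnb1, cyclin B1, at 49.9, 8.65, 54.6 and 16.2 CPM, and Ccna2, cyclin A2, at 153, 72.1, 178 and 64.8 CPM. In the cycling beta-like cluster Ube2c was at 679, 405, 532 and 709 CPM and Ccnb1 at 288, 180, 307 and 371 CPM. Trappc13 was at 46.6, 20.2, 78.9 and 18.01 CPM, and Ackr3, a chemokine receptor, at 286, 43.2, 103 and 72.0 CPM. Higher in both labelled mutants were Rgs5, a mark of pericytes, at 113, 182, 115 and 459 CPM against 2205 to 4666 CPM in mesenchymal-like cells, Enpp2, autotaxin, at 16.6, 121, 22.3 and 39.6 CPM, and Rnf141 at 29.9, 115, 42.5 and 77.4 CPM. Rgs4 had 0, 23, 2 and 15 counts. In this class 17, 30, 29 and 17 counts of Sin3a made 56.57, 86.48, 58.69 and 30.61 CPM, so low CPM rest on few counts. Sst was at 293, 8071, 243 and 209 CPM, and 13.0% of endothelial-like cells of the library labelled mutant A were insulin-rich, against 0.0% in the remaining libraries.

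With edgeR 0 of 6587 genes passed in endothelial-like cells, against 31 higher and 19 lower at an unadjusted p under 0.05, and DESeq2 gave 0 with 24 and 6. Without a filter on low counts 21 higher and 2 lower genes passed with edgeR. Leaving out the library labelled mutant B gave 83 and 18, WT A 9 and 1, WT B 9 and 3, and mutant A 1 and 0.

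Mesenchymal-like cells, which hold fibroblasts and pericytes, had Igfbp3, an insulin-like growth factor binding protein, at 315, 43.1, 294 and 155 CPM, a log2 difference of -1.54 ± 0.61 (SE), and Pdlim3, a muscle protein of actin filaments, at 104, 38.0, 126 and 52.6 CPM. Dusp2, a phosphatase, was at 25.7, 5.07, 205 and 29.6 CPM. Few counts lie behind low values, as Sin3a at 19.29, 55.79, 21.49 and 22.2 CPM had 12, 22, 13 and 27 counts here. Higher in both labelled mutants were Steap4, a metalloreductase, at 32.1, 81.1, 21.5 and 59.2 CPM, and Dck, deoxycytidine kinase, at 17.7, 58.3, 23.1 and 53.4 CPM. The make-up of the class differed between libraries: cluster 10, led by Rgs5 and Notch3, held 45 of 118, 59 of 66, 74 of 165 and 134 of 458 cells, and cluster 14, led by Tagln and Acta2, held 33, 0, 11 and 133. Markers of endocrine cells stood high in the library labelled mutant A, where 18.2% of cells were insulin-rich. Ttr was at 25.7, 563, 24.8 and 34.5 CPM against 1366 to 6144 CPM in alpha-like cells, and Sst at 350, 6758, 207 and 251 CPM. With edgeR 0 of 8219 genes passed, against 16 higher and 3 lower at an unadjusted p under 0.05, and DESeq2 gave 0 with 31 and 3. Without a filter on low counts 16 higher genes passed, without the library labelled mutant B 149 higher and 101 lower, and without mutant A 3 and 2.

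Over all cells together, Sin3a differed by 0.11 ± 0.57 (SE, log2), and 0 of 20040 genes passed with edgeR, against 20 higher and 5 lower at an unadjusted p under 0.05. DESeq2 gave 0 with 17 and 4. Leaving out the library labelled mutant B gave 33 higher and 23 lower genes, and leaving out WT A 1 higher.

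Cell classes were recovered in proportions that differed between libraries of the same label. Beta-like cells made up 36.5%, 40.8%, 32.9% and 28.8% of cells, and alpha-like cells 11.3%, 9.70%, 22.1% and 12.7%. Mesenchymal-like cells were at 9.78%, 5.77%, 9.20% and 19.2%, delta-like cells at 12.3%, 8.22%, 3.74% and 7.68%, and ductal-like cells at 2.32%, 1.31%, 5.41% and 7.51%. The cycling beta-like cluster held 9.20%, 10.6%, 5.63% and 6.51%, endothelial-like cells 5.05%, 4.72%, 4.96% and 6.09%, and pp-like cells 3.56%, 3.67%, 2.68% and 2.27%. The log2 difference between labels was 0.00 ± 0.43 (SE) for beta-like, -0.57 ± 0.59 for alpha-like and 0.40 ± 0.68 for mesenchymal-like cells. With edgeR on numbers of cells 0 of 14 classes differed, each with an adjusted p of 0.991 and none with an unadjusted p under 0.05, and exact permutation tests gave p of 0.667 to 1.0. These are shares of cells recovered after dissociation, not of the tissue. Clusters left without a name, mostly shallow cells, made up 5.63%, 10.5%, 6.64% and 2.81%.

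**Figure D4:**
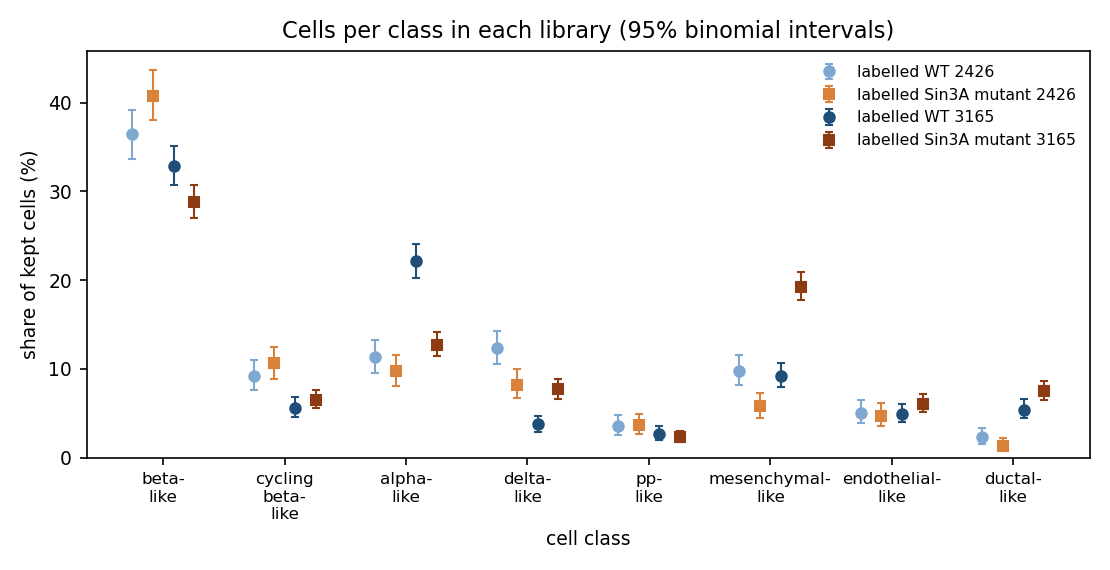
A and B stand for titles ending in _2426 and _3165. Share of kept cells (percent, vertical axis) in 8 cell classes (horizontal axis) for each of the 4 libraries, with exact 95% binomial intervals that cover counting error only. Mesenchymal-like cells reached 19.2% in the library labelled mutant B and 5.77% in that labelled mutant A, and alpha-like cells 22.1% in the library labelled WT B.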

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

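All tests in this part were chosen after the result was seen. Sin3a, an immediate early gene list and the insulin share of beta-like cells went opposite ways within A (titles ending in _2426) and B (_3165), each with 1 library per label, and the difference between the numbers was not tested. Sin3a in beta-like cells was higher in the library labelled mutant within A (log2 0.75) and lower within B (log2 -1.02). The immediate early and dissociation genes had a median change of 0.78 within A and -0.634 within B. The insulin share of beta-like counts was 13.8 percentage points higher in the library labelled mutant within A, and the difference was -4.29 within B.

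The pattern is that changes from labelled WT to labelled mutant in beta-like cells ran opposite in the numbers, with r = -0.72 across 9902 genes, which are not independent replicates. At equal totals and genes the beta-like r was -0.592 against -0.256 in endothelial-like cells, a difference of -0.336, and -0.658 against -0.185 in mesenchymal-like cells. Thinning equalled the counts but not the numbers of cells or the make-up of the classes. This gap therefore cannot decide on a difference in depth or handling that every cell class shares. Changes within A and B had r across genes with those of beta-like cells of 0.119 and 0.253 in endothelial-like and 0.189 and 0.182 in mesenchymal-like cells. In alpha-like cells these were 0.566 and 0.575, and in delta-like cells 0.592 and 0.517. Noise in the smaller sums was not separated. The beta-like r stayed at -0.707 thinned to the smallest library and -0.607 in cells of 3000 to 8000 counts, which argues against unequal counts alone. A handling difference shared by every class stays open, as r was negative in each of these classes. One shared by the endocrine classes alone stays open as well, with -0.66 against -0.599 in alpha-like and -0.632 against -0.487 in delta-like cells. Delta-like cells are not a separate witness, as many of them were insulin-rich. Without insulin-rich cells their r was -0.475 across 2245 genes, against -0.602 across 3404 genes with them. In alpha-like cells it was -0.571 without and -0.568 with them. RNA of other cell classes was argued against, since genes at least 2-fold higher in beta-like cells had r = -0.801. An exchange of the genotype labels of 1 number may account for the opposite signs, and a true difference between the animals or islets behind the numbers was not tested; both stay open, as the r of -0.72 is the pattern itself and decides nothing.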

How the results depend on the processing

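The alternatives other than those for cycling cells joined to a class, insulin-rich cells and the smaller classes were chosen before the data were examined, and the cause of a shift was not tested. Over 115 named genes in their classes, alternatives that kept every library gave 1376 values, of which 1354 kept direction and side of the threshold, 17 changed sign and 5 moved past the threshold. Leaving out each library in turn gave 459 values, of which 393 kept both, 49 changed sign and 17 moved past the threshold. Where 1 library of a label was left out, the lone library was taken to vary like the others. The counts of genes in beta-like, alpha-like and delta-like cells stayed at 0 under other scalings, DESeq2, the stricter filter, thinning and the cell filters, which in this design says little about stability.

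Without a filter on low counts edgeR called 23 genes in endothelial-like, 16 in mesenchymal-like and 39 in the smaller classes together, and 6 genes whose change differed between alpha-like and beta-like cells. Sin3a in beta-like cells changed sign to 0.00429 with the stricter filter, 0.0041 with doublets kept, 0.0749 with classes by hormone and 0.111 with cycling cells included. Sin3a in alpha-like cells was 0.0536 after thinning, and Sin3a in endothelial-like cells -0.00753 without a filter and -0.221 without insulin-rich cells. Adcy5 in beta-like cells was -0.155 with at most 10% mitochondrial counts, and Hbb-bs in beta-like cells 0.615 with classes by hormone. Cenpa in beta-like cells was 0.0177 with at least 1000 counts per cell, 0.323 with at most 10% mitochondrial counts, 0.138 without that limit, 0.151 with doublets kept and 0.0896 at resolution 2.

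The log2 share of beta-like cells changed sign to -0.00262 with at least 1000 counts per cell, -0.154 with at most 10% mitochondrial counts, -0.061 without that limit and -0.00595 with doublets kept. The share of cycling beta-like cells was -0.17 at resolution 2. The share of delta-like cells was 0.0199, 0.0386 and 0.0203 under the same cell filters and 0.16 with classes by hormone, and that of pp-like cells 0.0904 with at most 10% mitochondrial counts, 0.0206 at resolution 0.5 and 0.106 with classes by hormone. The difference in the cycling share of beta-like cells turned to 1.25, 2.29, 0.555 and 1.47 percentage points with at least 1000 counts, at most 10% mitochondrial counts, no such limit and doublets kept. Lists past the threshold in beta-like cells numbered 0 with an estimated correlation and 0 with fry, against 2 with camera's preset, and the apoptosis list turned sign with fry (adjusted p = 0.97).

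The title numbers behind A and B are each shared by 1 library of each label, and the titles do not say that they pair the libraries. With the number as a block, Hspa1a in beta-like cells was 0.303, Hspa1b in beta-like cells 0.304 and Sin3a in endothelial-like cells -0.0726. The log2 shares became -0.0148 in beta-like, 0.222 in delta-like and -0.105 in ductal-like cells, and 4 lists passed camera in alpha-like cells. The correlation across genes of same-number deviations from the label means was 0.0595 in beta-like, 0.244 in alpha-like, 0.134 in delta-like, 0.346 in pp-like, 0.123 in cycling beta-like, 0.506 in endothelial-like and 0.477 in mesenchymal-like cells, so none of these lay below -0.1.

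Leaving out each library in turn, counts of genes ranged from 0 to 1 in beta-like, 0 to 8 in alpha-like, 0 to 15 in delta-like, 0 to 56 over all cells, 0 to 37 in cycling beta-like, 1 to 101 in endothelial-like, 0 to 250 in mesenchymal-like and 0 to 10 in pp-like cells. They ranged from 0 to 7 for the difference between alpha-like and beta-like changes and from 11 to 398 over the smaller classes together. Sin3a ranged from -0.794 to 0.401 (log2) in beta-like, -0.879 to 0.361 in alpha-like, -0.496 to 1.14 in delta-like, -0.637 to 0.531 over all, -0.761 to 1.5 in cycling beta-like, -1.11 to 0.482 in pp-like and -0.867 to 0.657 in endothelial-like cells.

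Other genes that changed sign in beta-like cells were Zfp773 (-0.183 to 3.56), Cldn11 (-2.05 to 4.13), Pianp (-1.7 to 3.75), Tmprss2 (-2.88 to 0.222), Ogt (-0.969 to 1.51), Ing1 (-1.37 to 1.27), Ins1 (-1.68 to 1.48), Ins2 (-1.18 to 0.998), Ucn3 (-1.37 to 0.685) and Vamp2 (-1.41 to 1.27). Cdkn1a ranged from -0.204 to 1.51, Cenpa from -1.34 to 0.17, Cenpf from -0.0727 to 0.844, Cxcl12 from -0.287 to 1.3, Hk2 from -0.389 to 2.37, Cox7c from -1.25 to 1.46, Atp5b from -0.955 to 0.195, mt-Nd5 from -0.193 to 0.804 and mt-Nd1 from -1.28 to 1.3. Hspa1a ranged from -3.08 to 4.17, Hspa1b from -4.01 to 5.07, Psmb8 from -1.92 to 1.93, Cxcl10 from -1.29 to 0.236, Mvd from -1.14 to 0.127, Hmox1 from -1.65 to 1.17 and Mt1 from -2.85 to 3.25. Syt2 ranged from -0.0333 to 2.75, Hbb-bs from -1.46 to 1.36 and Hbb-bt from -0.288 to 2.71. In the other classes these were Tmsb15b2 in delta-like (-2.82 to 0.52), Cldn11 (-0.483 to 3.87) and Tmem67 (-0.081 to 2.81) in cycling beta-like, and Sst in endothelial-like (-0.312 to 4.99) and mesenchymal-like cells (-0.0778 to 4.63).

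Log2 shares of cells ranged from -0.268 to 0.235 for beta-like, -0.184 to 0.597 for cycling beta-like, -0.635 to 1.09 for delta-like, -1.57 to 0.946 for ductal-like, -0.0852 to 0.281 for endothelial-like, -0.717 to 1.02 for mesenchymal-like and -0.454 to 0.24 for pp-like cells. The insulin share difference ranged from -7.59 to 17.1 and the cycling share difference from -2.83 to 0.845 percentage points. Lists past camera's threshold numbered 2 to 5 in beta-like and 1 to 4 in alpha-like cells. Lists that changed direction had camera adjusted p of 0.0655 to 0.643 (Sin3 complex), 0.505 to 0.966 (islet transcription factors), 0.638 to 0.783 (calcium), 0.00042 to 0.525 (endoplasmic reticulum stress), 0.239 to 0.577 (apoptosis), 0.013 to 0.807 (disallowed genes) and 0.011 to 0.966 (glycolysis). These were 0.000119 to 0.602 for oxidative phosphorylation, 0.00115 to 0.766 for mitochondrially encoded, 7.58e-05 to 0.928 for immediate early, 0.35 to 0.928 for interferon, 0.148 to 0.896 for sterol and 0.000312 to 0.776 for hemoglobin lists, and 0.000331 to 0.76 for oxidative phosphorylation in alpha-like cells.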

Other observations

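All tests in this part were chosen after the result was seen. In beta-like cells the number separated libraries more than the label did: of the variance of log2 levels across genes 49.2% lay between numbers, 7.28% between labels and 43.5% in the crossed term. Genes with opposite changes within the numbers also included Dcx, a microtubule protein of young neurons, at 176, 54.0, 67.5 and 241 CPM, and Slc38a5, an amino acid transporter that is also among the alpha markers used here, at 386, 122, 84.7 and 394 CPM, in the order WT A, mutant A, WT B, mutant B. The early gene Arc stood at 29.8, 129, 74.2 and 12.6 CPM, and Ak1, adenylate kinase, at 13.7, 62.3, 94.7 and 12.2 CPM.

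Within the numbers, glucose sensing genes in beta-like cells had median changes of 0.22 and -0.11 (log2), at percentiles 99.2 and 6.89 of random lists, which describes these libraries only. Endoplasmic reticulum stress genes had -0.47 and 0.17 in beta-like cells, at percentiles 0.68 and 58.7, and -0.60 and 0.38 in alpha-like cells, at percentiles 0.13 and 99.5. Non-beta hormones had 0.78 and 0.39 in beta-like cells, at percentiles 99.9 and 80.2, from 5 genes of which 3 were higher and 2 lower in each number. Immediate early genes, at 0.78 and -0.63 in beta-like cells, had 0.12 and -0.12 in alpha-like cells.

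Differences between the numbers form another pattern. Splitting the libraries by number, edgeR called 43 genes in one direction and 155 in the other over all cells, 31 and 75 in endothelial-like, 11 and 61 in pp-like, 0 and 8 in delta-like and 0 and 3 in mesenchymal-like cells, against 0 for the label split, which points to a structure of the libraries. In beta-like, alpha-like and cycling beta-like cells edgeR called 0 genes by number, with 809 and 1324, 661 and 829, and 607 and 890 at an unadjusted p under 0.05, and the remaining way to split the 4 libraries gave 2 genes in endothelial-like and 0 in beta-like cells, with 914 and 842 unadjusted in beta-like cells against 16 and 1 for the label split. That remaining way sets WT A and mutant B against mutant A and WT B, the grouping that an exchange of labels in 1 number would give. Its counts cannot decide on such an exchange, as any crossed difference between libraries gives the same split. Across genes, which are not independent replicates, the change between numbers had r = 0.826 between beta-like and endothelial-like cells, so a difference in handling or sequencing that every class shares is a candidate explanation. A biological difference behind the numbers stays open, as the labels do not say what they stand for.

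Insulin-rich delta-like cells are a further pattern, 79 of 149 cells in WT A, 43 of 94 in mutant A, 0 of 67 in WT B and 63 of 183 in mutant B. Their median count was at least 1.63 times that of other delta-like cells in the 3 libraries that held them, which argues against free RNA, whose share is higher in shallower cells, and leaves droplets with 2 cells as a candidate explanation. Delta markers had 0.431, 0.468 and 0.463 times their share in other delta-like cells in WT A, mutant A and mutant B. In WT A 53.0% of delta-like, 6.62% of alpha-like, 9.30% of pp-like and 0.0% of endothelial-like cells were insulin-rich. In mutant A these shares were 45.7%, 0.0%, 21.4% and 13.0%. Random pairing of cells alone would give like shares in these classes, and why they differ was not tested. Other classes held fewer such cells and were not weighed: in mutant A the 12 mesenchymal-like and 7 endothelial-like ones were deeper than the rest (medians of 11126.5 against 3571 and 9382 against 5076), while 2 alpha-like ones in mutant B and 5 mesenchymal-like ones in WT B were shallower (1189 against 4489 and 1494 against 3563). Cells that make both hormones stay open and were not tested.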
